A study of Saccharomyces cerevisiae
Saccharomyces kudriavzevii with 63 samples.

How the data were processed

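Double-cut fragments were measured in 31 libraries of S. cerevisiae precipitates, each with a matching whole cell extract, and in 1 library of S. kudriavzevii. Per the labels' protocols, synchronous meiotic cultures of diploid SK1 strains were lysed, cells of S. kudriavzevii (strain ZP591) were added as a spike-in, Spo11-myc18 was precipitated with an anti-myc antibody, and DNA with unprotected ends was digested with exonuclease V on the beads. The submitters' processing notes name cutadapt 1.8.1 and Picard 1.119 without their roles, and the aligner is not given in the sources used here. Per the file headers, each deposited fragment file gives the chromosome, start and length of a fragment and its depth, a count of aligned fragments with that start and length, not normalized, on the SK1 assembly ASM205788v1 (chromosome 17 is mitochondrial). The deposited table of the series has 31 records, 1 per pair of precipitate and extract, with the authors' counts of fragments aligned to each species, the spike-in batch and a calibration factor, which is a ratio; 1 of its value columns was not used. The whole cell extracts entered through these counts alone. The calibrated amount was computed from the counts as the ratio of S. cerevisiae to S. kudriavzevii fragments in the precipitate over that in the extract, and the authors' factor is the same ratio divided by the precipitate's count. Replicates without a number in their title took the first unused one.

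The fragment files hold 95.5% to 100.0% of the counts in the series table. Mitochondrial fragments (0.0431% to 4.17% in the active libraries, 4.47% to 14.7% in the controls) were left out, as was 1 fragment past a chromosome end. No pair of replicates agreed within sampling noise over hotspots (chi-square per degree of freedom from 4.01 to 641). To call hotspots, midpoints of nuclear fragments of the 28 active libraries, each scaled to the same total, were averaged and smoothed with a 200 bp Hann window, and regions at or above 2.3 times the genome mean were kept, merged within 200 bp and required to be at least 25 bp wide. The period of a length distribution is that of the best least-squares fit between 8 and 13 bp, in steps of 0.01 bp, to the log histogram from 30 to 150 bp after a 21 bp running mean was removed. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.

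Amounts on the log2 scale, median lengths, shares and periods were compared with two-sided exact permutation tests, within backgrounds where there are 2, and with permutation tests of Pearson and Spearman correlations for the time course. Adjusted values are over the 11 planned tests of values, and over 20 tests of amounts by length and place, 12 of shares and 10 of differences between backgrounds that were added later. Fragment counts per hotspot were tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors on the hotspot totals, filterByExpr, which removed no hotspot) in 1 fit to all 28 active libraries with a level per group and 10 residual degrees of freedom, and called at an adjusted p under 0.05. Groups of hotspots were tested with camera of limma 3.58.1, with a preset correlation of 0.01. The comparisons, tests, hotspot groups and the rule for named hotspots were fixed before the data were examined. The rule takes the 10 strongest hotspots by mean share over the active libraries and, per comparison, the 5 largest rises and 5 largest falls among called hotspots at or above the median share that moved the same way in every pair of libraries; 133 hotspots met the second part after loss of Spo11 removal and 60 after loss of Tel1. Values are given in full for a few of them. Group means of a hotspot are in CPM, computed by edgeR over hotspot fragments with the TMM factors. Intervals of shares are Wilson 95% intervals and those of amounts are Wald 95% intervals on the log scale.

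Simulated counts for the 1701 hotspots, with 200 changed by known folds, tested the fit. At a 4-fold change it recovered 47.0% for the processing mutants, 71.2% for tel1∆, 15.2% for rec114-8A, 3.03% for wt at 5 h against 3.5 h and 12.1% for rad50S at 6 h against 4 h, with 0% to 9.09% false calls among all calls. At a 2-fold change it recovered 11.9% for tel1∆, 1.49% for rad50S and 0% for the other 3. Alternatives were DESeq2 1.42.0, total counts in place of TMM, no filter on low counts, 1000 bp bins, a hotspot threshold of 5, distinct fragments, hotspots without those higher in spo11Y135F, dual-index libraries, only the compared groups, other calibrations, length windows and summaries, and leaving out each library. Added after the data were seen were spike-in batch C alone (17 libraries, against 4, 2, 3 and 5 in batches A, B, E and F), batch as a covariate, and short or long fragments alone. The comparison of processing mutants and that of tel1∆ share the wt and rad50S libraries at 4 h, so their calls were not set against each other. Hotspots are named by position, because the gene table used here is of another assembly (S288C), and the planned lists that need an annotation of the SK1 assembly (promoters, gene bodies, known loci, centromeres, tRNA genes) were not analysed here. No group has enough libraries for a test of outlying libraries.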

Results

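Spo11 makes the DNA double-strand breaks of meiosis and stays attached to the DNA ends it has cut. The assay, Protec-Seq, precipitates myc-tagged Spo11 from meiotic diploid SK1 cells of Saccharomyces cerevisiae and digests DNA whose ends are not protected, so that pieces cut by Spo11 at both ends (double-cut fragments) are left for sequencing. The 31 S. cerevisiae libraries fall into 20 groups of genotype and hours in sporulation medium. Wild type (wt) has 2 libraries at 3.5 h, 3 at 4 h, 2 at 5 h and 1 at 6 h. At 4 h there are 2 libraries each of rad50S, mre11S, tel1∆, rad50S tel1∆ and rec114-8A rad50S, and 1 each of com1∆ and rec114-8A tel1∆. The rad50S strain also has 2 libraries at 6 h. Strains carrying Rec104-FRB-HA3, with or without rapamycin, have 6 libraries in RAD50 or rad50S cells, 1 per condition. The controls are 2 libraries of rad50S cells with the catalytically dead spo11Y135F and 1 of rad50S spo11∆ cells, all at 4 h.

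The 28 libraries with active Spo11 hold 135049 to 9399339 nuclear fragments, with a median of 4008322. The controls hold 552635 (spo11Y135F replicate 1), 47746 (spo11Y135F replicate 2) and 41705 (spo11∆) fragments. Spike-in cells of S. kudriavzevii gave 156415 to 13695600 fragments per library, and the amounts below are calibrated to them. The calibrated amount is the ratio of S. cerevisiae to S. kudriavzevii fragments in the precipitate, divided by the same ratio in the whole cell extract. Fragment midpoints were concentrated in 1701 regions, called hotspots here, with a median width of 218 bp, which cover 5.62% of the genome. Fragments were classed as short (up to 100 bp) or long (over 100 bp). Wilson 95% intervals of a single library's share are at most 0.671 percentage points wide for the share in hotspots, 0.805 for the share over 100 bp and 2.72 for the share over 100 bp among hotspot fragments. These intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples, which may be technical.

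In rad50S cells, fragments were far fewer without Spo11 activity than with it. In rad50S cells at 4 h the calibrated amount was 0.0789 and 0.00966 with spo11Y135F and 0.00326 with spo11∆. The 6 libraries they were compared with, of rad50S, rad50S tel1∆ and rec114-8A rad50S cells with active Spo11, gave 0.841 to 2.48, with a mean of 1.22 ± 0.623 (SD, n = 6). The 3 controls averaged 0.031 ± 0.042 (SD, n = 3), and hotspots held 9.71% to 16.8% of their fragments against 44.6% to 92.0% in those 6. The rad50S library with Rec104-FRB-HA3 at 4 h, which was not in this test, gave 0.502, with 43.6% in hotspots. Nor were the wt libraries, whose lowest amount was 0.122 (4 h replicate 2, with 40.5% in hotspots), not far above the 0.0789. All 3 controls lay below all 6 libraries (mean log2 difference -6.38, two-sided exact permutation test, p = 0.0119, the smallest possible, and 0.0917 after Benjamini-Hochberg over 11 tests). In the hotspots alone, the short fragments were 499-fold and the long fragments 399-fold lower in the controls, in tests chosen after the data were examined (exact p = 0.0119 each, 0.0510 after Benjamini-Hochberg over 20 tests). Hotspots were called from the 28 active libraries alone, these 6 included. The hotspot shares and hotspot amounts are thus partly set by the calling and are not independent evidence. Within spike-in batch C, which holds 2 of the 3 controls, the difference was -5.88 (exact permutation p = 0.0667, too few libraries for a lower value), and the hotspot amounts were 280-fold and 290-fold lower (exact p = 0.0667 each). In 145 of the 1701 hotspots the mean share of fragments was higher in spo11Y135F than in the active libraries.

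Double-cut fragments had preferred lengths, spaced by about 1 turn of the DNA helix. In each of the 8 wt libraries the 2 highest peaks of the length distribution lay at 56 or 57 bp and at 67 bp, and other peaks followed at a similar spacing. The period of the length distribution was 10.57 bp ± 0.020 (SD, n = 28) over the active libraries and lay between 10.53 and 10.63 bp in each. The periodic part made up 36.0% to 74.0% of the variance of the detrended distribution in the active libraries and 10.5% to 18.8% in the controls. The period did not differ detectably between the 5 processing mutant libraries described next (10.57 bp ± 0.018, SD, n = 5) and the 3 wt libraries at 4 h (difference -0.013 bp, two-sided exact permutation test, p = 0.393, 0.540 after Benjamini-Hochberg over 11 tests). The sign of this difference turned under 3 alternatives, and with a 15 bp running mean it was 0.033 bp (exact permutation p = 0.0357).

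**Figure D1:**
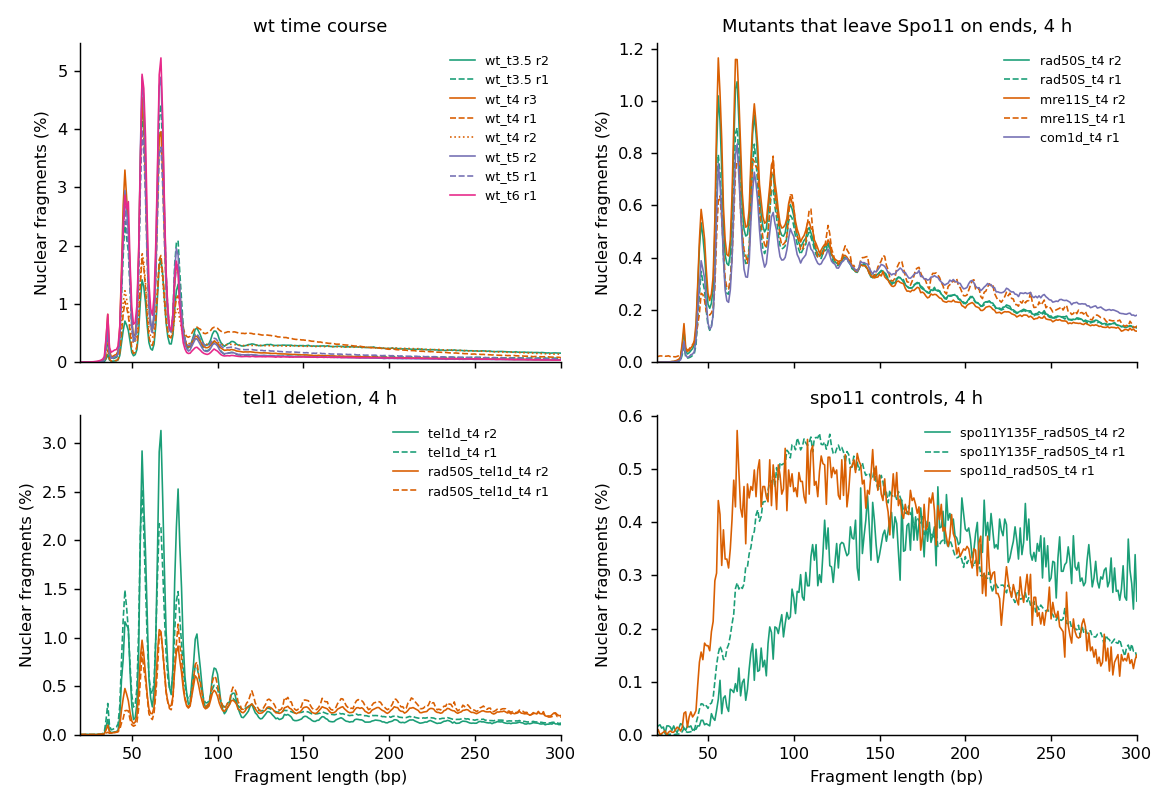
Length distribution of nuclear fragments, with fragment length in bp on the x axis and the percentage of the library's nuclear fragments on the y axis (scales differ between panels), 1 line per library for the wt time course, the mutants that leave Spo11 on the ends, the tel1∆ strains and the spo11 controls. Peaks recur about every 10.6 bp in the active libraries. The main peaks lie below 100 bp in wt and in the mutants rad50S, mre11S and com1∆. These mutants carry a tail of longer fragments, as do some wt lines. Fragments over 100 bp make up 62.9% to 74.4% of nuclear fragments in these mutants and 16.7% to 64.7% in wt.

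The next comparison asks what accumulates when Spo11 cannot be removed from the ends. Rad50, Mre11 and Com1 (also called Sae2) act together to release Spo11 from break ends, and rad50S, mre11S and com1∆ block that step. In these mutants, hotspot fragments over 100 bp were more abundant, while those up to 100 bp did not differ detectably from wt. Long hotspot fragments reached a calibrated amount of 0.249 ± 0.138 (SD, n = 5) against 0.027 ± 0.016 (SD, n = 3) in wt at 4 h, 9.29-fold higher. All 5 mutant libraries lay above all 3 wt libraries. Short hotspot fragments were at 0.129 ± 0.049 (n = 5) and 0.154 ± 0.113 (n = 3). Fragments over 100 bp made up 62.3% ± 3.36 (SD, n = 2) of hotspot fragments in rad50S, 65.3% ± 12.2 (n = 2) in mre11S and 67.4% in com1∆ (n = 1), against 18.8% ± 9.80 (n = 3) in wt.

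The test of the long hotspot fragments passed before but not after adjustment (two-sided exact permutation p = 0.0179, the smallest possible, 0.0510 after Benjamini-Hochberg over 20 tests). Within batch C the difference was 7.71-fold (exact p = 0.0286). For the short ones the log2 difference was 0.055 over all libraries (exact p = 0.929, 0.944 after adjustment) and -0.059 within batch C (exact p = 0.971). This split by length and place was chosen after the data were examined. Over all fragments, the calibrated amount averaged 0.760 ± 0.327 (SD, n = 5) in the mutants and 0.379 ± 0.242 (SD, n = 3) in wt. The log2 difference of 1.16 did not pass its test (exact permutation p = 0.125, 0.263 after Benjamini-Hochberg over 11 tests). Among the mutants, rad50S gave 0.870 and 0.997, mre11S 1.10 and 0.485, and com1∆ 0.350. The median length of all fragments was 148.4 bp ± 14.7 (SD, n = 5) in the mutants and 105.0 bp ± 33.9 (SD, n = 3) in wt, 43.4 bp longer (exact permutation p = 0.0357, 0.131 after Benjamini-Hochberg over 11 tests). Of the 5 mutant libraries, 4 lay above the highest wt library. Within batch C the difference in median length was 42.5 bp (exact permutation p = 0.0857). The exact p was above 0.05 when 1 of these libraries was left out, namely com1∆ (39.3 bp), rad50S replicate 1 (41.0 bp) or 2 (46.0 bp), mre11S replicate 1 (42.5 bp), or wt replicate 1 (48.9 bp) or 3 (24.4 bp).

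**Figure D2:**
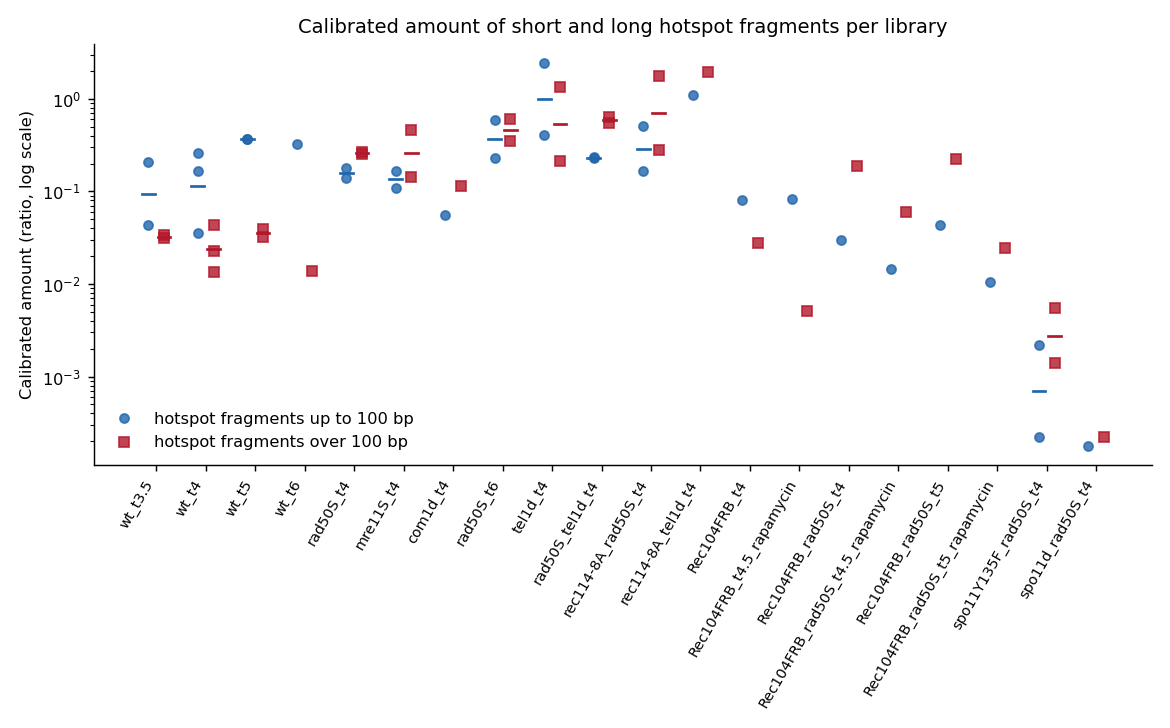
Calibrated amount of hotspot fragments (ratio, log scale) on the y axis for each group on the x axis, with 1 blue circle (up to 100 bp) and 1 red square (over 100 bp) per library and a short line at the geometric mean of groups with more than 1 library. Long fragments average 0.249 in rad50S, mre11S and com1∆ at 4 h and 0.027 in wt at 4 h, while short fragments average 0.129 and 0.154.

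Single hotspots changed in both directions in these mutants. Rises were more frequent than falls in the strong hotspots and on the short chromosomes, and falls near chromosome ends, but as groups these did not pass with an estimated correlation between hotspots. Among the 133 changed hotspots at or above the median share that moved the same way in every pair of libraries, the largest rise was on chromosome 4 at 687216 to 688939 (coordinates of the SK1 assembly ASM205788v1). It was 6.78-fold higher in the mutants, at 2047 ± 167 CPM (hotspot fragment counts scaled by library total and TMM factor, which are not shares of the total; SD, n = 5) against 307 ± 227 CPM (n = 3) in wt (log2 2.76 ± 0.77 SE, adjusted p = 0.0251, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as for all hotspot tests below). Over 19 alternatives its log2 value ranged from 1.33 to 3.93, and it did not pass in 5. The hotspot on chromosome 12 at 114900 to 115254 fell from 883 ± 206 CPM (n = 3) to 209 ± 97.1 CPM (n = 5) (log2 -2.20 ± 0.38 SE, adjusted p = 0.00452 by edgeR). Of the 10 strongest hotspots, 4 rose, among them the one on chromosome 3 at 211652 to 222789, with 33273 ± 12470 CPM (n = 5) against 8629 ± 2080 CPM (n = 3) (log2 1.87 ± 0.36 SE, adjusted p = 0.00505 by edgeR). In all, 340 of 1701 hotspots changed, 158 up and 182 down.

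Among the same 133, the next largest rises lay on chromosome 2 at 649514 to 649972 (log2 2.48), chromosome 7 at 835999 to 836462 (2.40) and chromosome 10 at 568469 to 569014 (2.39) and 575016 to 576579 (2.34), with adjusted p from 0.0160 to 0.0289 by edgeR. The other falls named by this rule lay on chromosome 12 at 382177 to 382369 (log2 -2.64) and 385076 to 385440 (-2.47), chromosome 3 at 131245 to 131508 (-2.17) and chromosome 16 at 24787 to 25001 (-2.11), with adjusted p from 0.00370 to 0.0285 by edgeR. Each of the other named rises did not pass in 2 to 6 of the 19 alternatives, except chromosome 3 at 211652, which passed in all, and the named falls did not pass in 0 to 4. Besides chromosome 3 at 211652, the strongest hotspots that rose were those on chromosome 4 at 821881 to 826173 (log2 2.08), chromosome 13 at 765272 to 771905 (1.71) and chromosome 8 at 183852 to 189191 (1.34). The other 6 had log2 values of 0.80 to 1.26 and did not pass, including chromosome 6 at 116251 to 118508 (0.80, adjusted p = 0.226 by edgeR) and chromosome 1 at 192438 to 196423 (0.97, adjusted p = 0.239 by edgeR).

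On the short chromosomes 1, 3 and 6, 55 of 208 hotspots rose and 4 fell (70 and 7 adjusted over the list alone), with a median log2 change of 0.77 against -0.17 elsewhere. In the highest decile of hotspots by mean share, 27 rose, 1 fell and 143 did not pass (25 rose and 1 fell adjusted over the list alone), with a median of 0.74. Within 20 kb of chromosome ends, 1 of 18 rose and 5 fell (1 and 7 adjusted over the list alone), with a median of -1.23, and within 50 kb 6 of 122 rose and 38 fell (6 and 52 adjusted over the list alone), with a median of -1.02. The adjusted p of camera, which compares a group with all other hotspots, was 1.32e-10, 1.21e-09, 0.0175 and 3.39e-08 for these 4 groups. The first 3 values are adjusted over 25 tests, and that within 50 kb over 5 tests. With an estimated correlation between hotspots the camera adjusted p was 0.270, 0.457 and 0.270 for the first 3 groups. In none of the 5 comparisons did a group pass camera with an estimated correlation, which was not run for the 50 kb distance. The long chromosomes 4, 7 and 15 (42 of 474 rose, 29 fell; 24 and 21 adjusted over the list alone; median 0.18) and the lowest decile (17 rose, 18 fell; 27 and 20 adjusted over the list alone) did not stand apart, with camera adjusted p of 0.0572 and 0.464. The deciles were chosen on these same samples, so their direction is not independent evidence.

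Measured as a share of each library's hotspot fragments, chromosomes 1, 3 and 6 held 16.5% ± 0.946 (SD, n = 5) in the mutants and 13.4% ± 0.497 (SD, n = 3) in wt. The difference was 3.03 points (exact permutation p = 0.0179, the smallest possible, 0.0536 after Benjamini-Hochberg over 12 tests; 3.29 points, exact p = 0.0286, within batch C). The background is close to the mutants' value, with 17.4% ± 0.665 (SD, n = 2) in spo11Y135F and 15.9% in spo11∆, although hotspots held few of the fragments there. The 10 strongest hotspots held 17.3% ± 1.93 against 11.4% ± 0.468, 5.87 points more (exact p = 0.0179, 0.0536 adjusted; 5.06 points, exact p = 0.0286, within batch C). Hotspots within 50 kb of an end held 4.14% ± 0.491 against 5.53% ± 0.775, a difference of -1.39 points (exact p = 0.0357, 0.0857 adjusted; -1.59 points, exact p = 0.0286, within batch C). These tests of shares, here and below, were chosen after the data were examined. The 10 strongest hotspots were ranked on these same samples, so the direction of their difference is not independent evidence.

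The balance of rises and falls rests on how libraries are scaled. Scaling to the total hotspot count moved the median log2 change of all hotspots by -0.66 and gave 15 rises and 431 falls. Scaling by DESeq2 moved it by -0.10 and gave 269 and 331. The medians of chromosomes 1, 3 and 6 (0.67 with DESeq2, 0.10 with total counts) and of the highest decile (0.65 and 0.039) stayed positive. Those near ends stayed negative (-1.33 and -1.90 within 20 kb), and that of chromosomes 4, 7 and 15 turned negative with total counts (-0.48). The number of changed hotspots rested on single libraries, with 56 without wt replicate 3, 127 without wt replicate 1, and 145 or 189 without rad50S replicate 1 or 2. Within batch C 1001 hotspots changed (444 up, 557 down), and with batch as a covariate 889 (428 up, 461 down).

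Tel1, the yeast counterpart of the kinase ATM, is known to limit further breaks near a break, and its deletion was compared with TEL1 in RAD50 and in rad50S cells. Taken over all fragments, the calibrated amount was higher without Tel1 in all 4 libraries. In RAD50 cells the calibrated amount was 1.01 and 4.41 without Tel1 against 0.379 ± 0.242 (SD, n = 3) in wt, and in rad50S cells it was 1.07 ± 0.015 (SD, n = 2) against 0.934 ± 0.090 (SD, n = 2). In hotspots, short fragments were 3.56-fold and long ones 7.15-fold higher without Tel1 over both backgrounds. On the log2 scale the short ones were higher by 3.10 in RAD50 and 0.56 in rad50S cells, and the long ones by 1.17 in rad50S cells and by more in RAD50 cells. Outside hotspots the backgrounds went opposite ways. The log2 differences of short and long fragments there were 1.58 and 1.77 in RAD50 cells and -1.28 and -1.04 in rad50S cells. Over both backgrounds neither passed (exact permutation p = 0.85 and 0.65). Fragments over 100 bp made up 35.2% ± 0.442 (SD, n = 2) of hotspot fragments in tel1∆ and 71.6% ± 1.53 (SD, n = 2) in rad50S tel1∆, against 18.8% ± 9.80 (SD, n = 3) in wt and 62.3% ± 3.36 (SD, n = 2) in rad50S.

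Over both backgrounds the calibrated amount was higher by 1.48 on the log2 scale, a difference that passed before but not after adjustment (2.76 in RAD50 and 0.20 in rad50S cells; two-sided exact permutation test within backgrounds, p = 0.0167, the smallest possible, 0.0917 after Benjamini-Hochberg over 11 tests). The hotspot amounts of both lengths gave exact p = 0.0167 (0.0510 adjusted over 20 tests). Within batch C they were 2.24-fold (exact p = 0.25) and 4.36-fold (exact p = 0.0833) higher. The larger effect in RAD50 cells was not shown to differ from that in rad50S cells (difference 2.56, exact permutation p = 0.15, 0.476 after Benjamini-Hochberg over 10 tests). Nor were those of the short (2.54, exact p = 0.3) and long hotspot fragments (3.33, exact p = 0.233), with 0.476 after adjustment for both. The median length of all fragments was 12.5 bp lower without Tel1 in RAD50 cells (difference -12.5 bp) and 33.0 bp higher in rad50S cells, 10.25 bp higher on average (exact permutation p = 0.533, 0.587 adjusted; difference between backgrounds, exact p = 0.183, 0.476 adjusted over 10 tests). Among hotspot fragments alone, the median was 27.9 bp higher (exact p = 0.0167) and the share over 100 bp 12.9 points higher (exact p = 0.0333) without Tel1. Over all fragments the share over 100 bp differed by 1.39 percentage points (-1.36 and 4.13; exact permutation p = 0.933 before and after adjustment). It turned without tel1∆ replicate 1 (-0.51), wt replicate 3 (-4.49) or rad50S replicate 2 (-0.21). The higher amount rests on tel1∆ replicate 2, with 0.94 without it (exact p = 0.292) and 0.95 within batch C (exact p = 0.333). It no longer passed without wt replicate 1 (1.71), 2 (1.14) or 3 (1.58), each with exact p = 0.0556, the smallest for that number of libraries.

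Without Tel1, 92 of 1701 hotspots changed relative to the rest, 76 up and 16 down, and the rises included the strongest hotspots of the short chromosomes. The hotspot on chromosome 1 at 192438 to 196423 reached 68520 ± 49364 CPM (SD, n = 4) without Tel1 against 10433 ± 2097 CPM (SD, n = 5) with it (log2 2.54 ± 0.54 SE, adjusted p = 0.0258, edgeR). The one on chromosome 6 at 116251 to 118508 reached 67399 ± 39121 CPM (n = 4) against 20407 ± 4737 CPM (n = 5) (log2 1.62 ± 0.42 SE, adjusted p = 0.0439, edgeR). On chromosome 3, the hotspots at 163619 to 163992 (log2 2.73 ± 0.48 SE, adjusted p = 0.00929, edgeR), 320621 to 320779 (2.77) and 211652 to 222789 (1.34) rose. Hotspots on chromosome 6 at 127500 to 127955 (2.32) and chromosome 10 at 401759 to 402989 (2.26) rose too. The falls named by the rule were on chromosome 4 at 224864 to 225269 (log2 -1.27, adjusted p = 0.0470, edgeR) and 1406932 to 1407142 (-0.97, adjusted p = 0.0489, edgeR). They did not pass in 12 and 11 of 20 alternatives (log2 -1.93 to -0.78 and -1.70 to -0.85), and each of the named rises did not pass in 5 to 10. No hotspot passed the test of a difference between RAD50 and rad50S cells by edgeR (0 at adjusted p under 0.05, 113 at unadjusted p under 0.05, 24 by DESeq2).

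On chromosomes 1, 3 and 6, 25 of 208 hotspots rose without Tel1 and 0 fell (40 and 0 adjusted over the list alone), with a median log2 change of 0.42. The median was 0.32 with DESeq2 and -0.29 with total counts, so the direction of the group holds only relative to the other hotspots (-0.79 with total counts). In the highest decile, 29 rose, 0 fell and 142 did not pass (57 rises and 0 falls adjusted over the list alone), with a median of 0.94 (0.81 with DESeq2, 0.048 with total counts). That median was 0.28 within batch C and 0.41 with batch as a covariate. In the lowest decile, 1 rose and 3 fell (0 and 0 adjusted over the list alone), with a median of -0.51 (-0.64 and -1.24). The camera adjusted p of these groups was 1.79e-05, 1.01e-20 and 6.42e-05 over 25 tests. It was 0.446, 0.270 and 0.505 with an estimated correlation. Hotspots of chromosomes 4, 7 and 15 (19 rose, 4 fell; 15 and 0 adjusted over the list alone) and those within 20 kb of ends (2 rose, 0 fell) had camera adjusted p of 0.538 and 0.464. As a share of hotspot fragments, chromosomes 1, 3 and 6 held 27.0% ± 2.32 (SD, n = 2) in rad50S tel1∆ against 16.3% ± 1.11 (SD, n = 2) in rad50S, and 15.6% ± 1.70 (SD, n = 2) in tel1∆ against 13.4% ± 0.497 (SD, n = 3) in wt. The mean difference was 6.45 points (exact permutation p = 0.0167, the smallest possible, 0.0536 after Benjamini-Hochberg over 12 tests; 6.23 points, exact p = 0.0833, within batch C). It was not shown to differ between RAD50 (2.18 points) and rad50S cells (10.7 points; exact permutation p = 0.333, 0.476 adjusted over 10 tests). The 10 strongest hotspots held 6.07 points more without Tel1 (exact permutation p = 0.0167, 0.0536 adjusted, and 3.86 points, exact permutation p = 0.0833, within batch C). They were ranked on these same samples, so the direction is not independent evidence. Hotspots within 50 kb of ends held 2.23 points more without Tel1, which did not pass (exact p = 0.0667, 0.133 adjusted; 1.77 points, exact p = 0.167, within batch C), with 7.89% against 4.09% in rad50S and 6.19% against 5.53% in RAD50 cells.

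**Figure D3:**
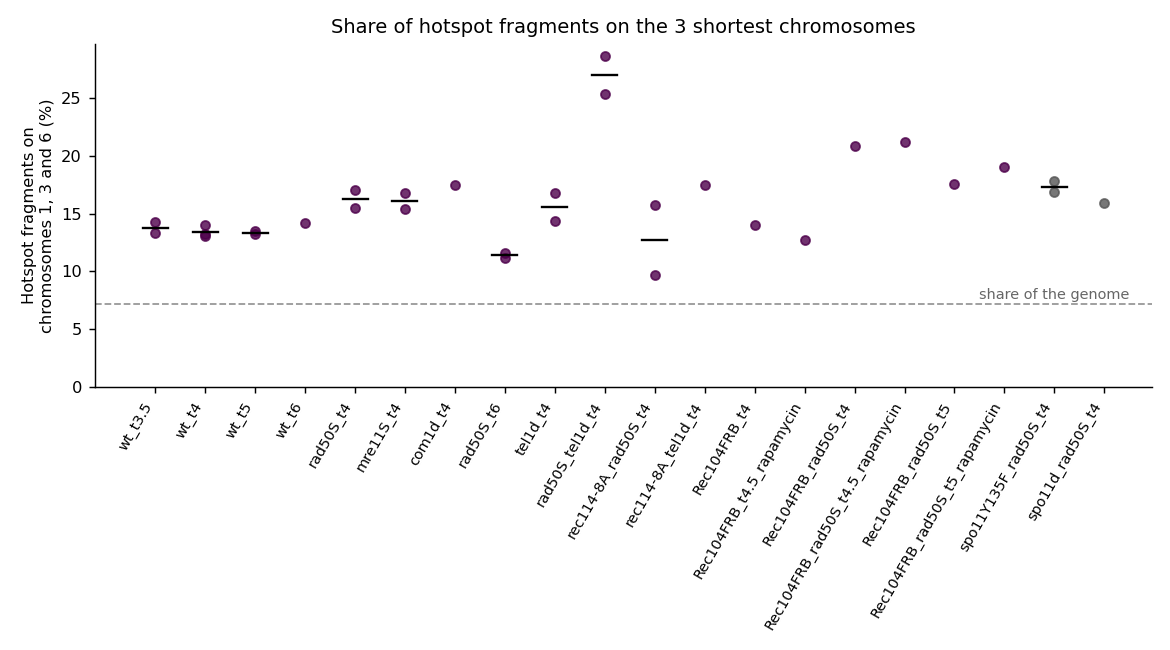
Percentage of each library's hotspot fragments that lie on chromosomes 1, 3 and 6 (y axis) for each group (x axis), with 1 point per library (grey for the spo11 controls), a line at the mean of groups with more than 1 library, and a dashed line at these chromosomes' share of the genome, 7.21%. The share is 27.0% in rad50S tel1∆, 16.3% in rad50S at 4 h, 11.4% in rad50S at 6 h and 13.4% in wt at 4 h, and 15.9% to 17.8% in the controls.

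These counts depend on the libraries, the scaling and the fragment length. Of the 92 called hotspots, 2 passed with short fragments alone and 71 with long ones alone. Without rad50S replicate 1 or 2, 0 hotspots passed by edgeR, and 2, 3, 9, 11 or 10 passed without rad50S tel1∆ replicate 1, tel1∆ replicate 2, or wt replicate 1, 2 or 3. In contrast, 421 passed without tel1∆ replicate 1 and 275 without rad50S tel1∆ replicate 2. Scaling to the total hotspot count moved the median by -0.76 and gave 15 rises and 53 falls, and DESeq2 moved it by -0.13 and gave 146 and 124. Within batch C there were 81 rises and 63 falls.

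Rec114-8A carries changes at sites that Tel1 and the related kinase Mec1 phosphorylate in Rec114, a protein that Spo11 needs for cutting. Median fragment lengths were higher on average than in the matching strains with normal Rec114, without passing the test. The median was 169.5 bp ± 14.8 (SD, n = 2) in rec114-8A rad50S against 148.0 bp ± 14.1 (SD, n = 2) in rad50S, and in rec114-8A tel1∆ (n = 1) it was 80.5 bp above the 92.5 bp ± 9.19 (SD, n = 2) of tel1∆. The calibrated amounts were 0.841 and 2.48 against 0.870 and 0.997 in rad50S cells, and 4.04 against 1.01 and 4.41 in tel1∆ cells. The mean difference in median length was 51.0 bp (21.5 and 80.5 bp; two-sided exact permutation test, p = 0.0556, the smallest these 7 libraries allow, 0.153 after Benjamini-Hochberg over 11 tests). Among fragments of 30 to 200 bp it was 9.5 bp (exact p = 0.278), and in batch C the rec114-8A rad50S library had a median of 159 bp against 158 and 138 bp in rad50S. The mean log2 difference in amount was 0.79 (0.63 and 0.94; exact permutation p = 0.5, 0.587 adjusted). Between libraries of the same spike-in batch it was -0.15 in rad50S cells (batch C) and -0.13 in tel1∆ cells (batch A). In hotspots, short fragments were 1.44-fold (exact p = 0.611) and long ones 3.14-fold (exact p = 0.222) higher. Of the long ones, rec114-8A rad50S replicate 2 (batch B) had an amount of 1.77, and replicate 1 (batch C) 0.283 against 0.254 and 0.267 in rad50S.

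No single hotspot passed edgeR's quasi-likelihood test in rec114-8A rad50S against rad50S (0 of 1701 at adjusted p under 0.05, 204 at unadjusted p under 0.05, 0 by DESeq2). In simulated counts this test recovered only 15.2% of 4-fold changes. The strong hotspots on chromosome 6 at 116251 and chromosome 1 at 192438 were higher without passing (log2 1.34 and 1.21), and that on chromosome 3 at 211652 was at 0.065. The highest decile had a median log2 difference of 1.09, the lowest -0.54 and chromosomes 1, 3 and 6 -0.50, with 0 members passing in each list, also adjusted over the list alone. Their camera adjusted p was 3.19e-16, 4.24e-07 and 4.09e-06, and 0.360, 0.398 and 0.398 with an estimated correlation. These group differences rest on replicate 2. Within batch C, which leaves replicate 1, the medians were 0.097, 0.0069 and -0.037. The share of hotspot fragments on chromosomes 1, 3 and 6 was 15.7% in replicate 1 and 9.69% in replicate 2. Without replicate 1, 348 hotspots passed (257 up, 91 down). Scaling to total counts moved the median of all hotspots by -0.59, which leaves the highest decile at 0.074, the lowest at -0.88 and chromosomes 1, 3 and 6 at -0.86.

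The wt time course follows double-cut fragments from 3.5 to 6 h. Mean amounts were higher from 4 h on than at 3.5 h and the share of long fragments among hotspot fragments was lower at each later time, but neither trend with time, in amount or median length, passed its test. The calibrated amount averaged 0.228 ± 0.113 (SD, n = 2) at 3.5 h and 0.379 ± 0.242 (SD, n = 3) at 4 h. It was 0.586 ± 0.076 (SD, n = 2) at 5 h and 0.428 at 6 h. Long fragments made up 28.5% ± 21.9 (SD, n = 2) of hotspot fragments at 3.5 h, 18.8% ± 9.80 (n = 3) at 4 h, 8.01% and 9.59% at 5 h and 4.08% at 6 h. Hotspots within 50 kb of chromosome ends held 4.87% ± 0.702 (SD, n = 2) of hotspot fragments at 3.5 h, 5.53% ± 0.775 (n = 3) at 4 h, 7.15% ± 0.0863 (n = 2) at 5 h and 8.22% at 6 h.

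Over the 8 libraries, all of batch C, the amount correlated with time at Pearson r = 0.508 (permutation p = 0.190) and Spearman rho = 0.605 (permutation p = 0.118), with 0.299 after Benjamini-Hochberg over 11 tests. The median length correlated with time at r = -0.551 (permutation p = 0.143) and rho = -0.655 (permutation p = 0.0869), with 0.263 adjusted. Without the libraries farthest in time, namely that at 6 h and 1 of those at 5 h, r was 0.57 or 0.50 for the amount and -0.39 or -0.42 for the length, depending on which 5 h library was left out (permutation p from 0.25 to 0.517). Without replicate 1 at 3.5 h the length passed (r = -0.749, permutation p = 0.0381). Between 3.5 and 5 h no hotspot passed edgeR's quasi-likelihood test (0 at adjusted p under 0.05, 69 at unadjusted p under 0.05, 1 by DESeq2). In simulated counts this test recovered only 3.03% of 4-fold changes, so it does not show that hotspots stayed the same. The strong hotspots on chromosomes 6 at 116251, 1 at 192438 and 3 at 211652 had log2 values of -0.16, 0.17 and -0.38. As groups, hotspots within 20 kb (median log2 0.44) and 50 kb of ends (0.58) were higher and those of chromosomes 1, 3 and 6 lower (-0.27) at 5 h, with the same signs under both other scalings. In each list 0 members passed, also adjusted over the list alone. Their camera adjusted p was 0.0161, 7.35e-14 and 0.0261, over 25 tests except within 50 kb, where it is over 5 tests. With an estimated correlation it was 0.270 within 20 kb of ends and 0.660 for chromosomes 1, 3 and 6.

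In rad50S cells, the double-cut fragments at 6 h were compared with those at 4 h. The amount at 6 h was 1.25 and 2.26 against 0.870 and 0.997 at 4 h, a log2 difference of 0.85 (exact permutation p = 0.333, the smallest that 2 against 2 allows). The short chromosomes held less at 6 h, with 11.4% ± 0.354 (SD, n = 2) of hotspot fragments on chromosomes 1, 3 and 6 against 16.3% ± 1.11 (SD, n = 2) at 4 h, 4.90 points less (difference -4.90 points, exact permutation p = 0.333, 0.444 after Benjamini-Hochberg over 12 tests). By edgeR's quasi-likelihood test 0 single hotspots passed (86 at unadjusted p under 0.05, 9 by DESeq2). In simulated counts this test recovered only 12.1% of 4-fold changes. With the compared groups alone in the fit 761 changed, and with dual-index libraries alone 126. The strong hotspots on chromosomes 6 at 116251, 1 at 192438 and 3 at 211652 were at log2 -0.28, -0.55 and -0.86. The hotspots of chromosomes 1, 3 and 6 had a median log2 difference of -0.79, -0.76 with either other scaling, and 0 of 208 passed, also adjusted over the list alone. Against the other hotspots the camera adjusted p was 1.67e-25 over 25 tests, and 0.193 with an estimated correlation. Hotspots within 50 kb of ends had a median of 0.27 (camera adjusted p = 0.0106 over 5 tests). Within 20 kb the median was 0.37 (camera adjusted p = 0.464). The lowest decile had a median of -0.34 (camera adjusted p = 0.0175, 0.660 with an estimated correlation). The 4 h libraries are of spike-in batch C and the 6 h libraries of batches E and F, so batch and time cannot be told apart here.

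Rapamycin was added at 4 h to strains in which Rec104, a partner of Spo11 needed for cutting, is fused to FRB, a tag that lets rapamycin move a protein out of the nucleus. In rad50S cells, which keep Spo11 on the ends, the calibrated amount after rapamycin was 0.182 at 4.5 h against 0.502 at 4 h, when the drug was added, and 0.0794 against 0.557 at 5 h without the drug. The first is 36.2% of the untreated value and the second 14.3%, with Wald 95% intervals from the counts of 35.9% to 36.5% and 14.1% to 14.4%. Short hotspot fragments were 2.02-fold and long ones 3.12-fold lower at 4.5 h, and 4.10-fold and 9.13-fold lower at 5 h. The 0.0794 is close to the 0.0789 of the control spo11Y135F replicate 1, of another batch, so much of it may be background. The other controls gave 0.00966 and 0.00326. In hotspots, this library's amounts were 0.0106 (short) and 0.0244 (long), against 0.00217 and 0.00549 in spo11Y135F replicate 1. In RAD50 cells the amount was 0.146 at 4.5 h with the drug and 0.257 at 4 h without it, or 56.7% (log2 difference -0.82, Wald 95% interval -0.84 to -0.80). There the long hotspot fragments were 5.44-fold lower, while the short ones differed by a log2 value of 0.024. Each condition has 1 library, so these differences have no replicate check, and the untreated libraries of the 4.5 h comparisons are from 4 h.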

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

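The tests of this part were chosen after the results were seen. The library of S. kudriavzevii alone (com1∆ at 6 h) enters no comparison. Its deposited file is marked as made without exonuclease V, which the labels do not state. Its fragment lengths were periodic too, with a period of 10.59 bp that made up 53.7% of the variance of the detrended length distribution, against 10.5% to 18.8% in the S. cerevisiae controls. No control library of that species was analysed here, and no explanation was tested.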

How the results depend on the processing

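Groups hold 1 to 3 libraries, which limits these results. The limit set by depth was not measured, since the counting intervals of shares, at most 2.72 points wide, treat PCR reads as independent molecules. The 77 results were recomputed under 866 alternatives. For the 32 results of named hotspots, 301 alternatives kept the direction and side of the threshold, 34 lost the call, 3 gained one and 8 turned; with 1 library left out, 143 kept both, 81 lost the call, 1 gained one and 4 turned. For amounts and lengths, 48 alternatives kept both, 9 lost the call, 2 gained one, 7 turned and 11 moved; with 1 library left out, 78 kept both, 10 lost the call, 1 gained one and 3 turned. Of the hotspot counts, 39 stayed within 1.5 times and 24 did not (15 and 14 with 1 library left out), and of the group tests 16 kept the call, 13 lost it and 1 gained one. The alternatives with spike-in batch C, batch as a covariate, and short or long fragments alone were chosen after seeing the data. The authors' calibration factor gives the same amounts by construction, and leaving out the filter, which removed no hotspot, gives the same hotspot tests. Both are nevertheless counted above among the alternatives that held. So are named hotspots without a call that stayed without one. Dual-index or batch alternatives that leave out no library, or all of a group, gave no value. No paired analysis was possible because the compared groups share number 1 alone in the labels; the other shared numbers were given here to titles without one. Where a result below did not hold, the cause was not tested.

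The control difference kept its direction (-7.65 to -5.35 with 1 library left out) but did not pass with dual-index libraries or batch C (-5.88 in both). The amount in processing mutants ranged from 0.48 to 1.63 with 1 library left out and was 0.036 without calibration and 0.055 for short hotspot fragments, never passing. Their median length ranged from 24.4 to 56.9 bp, with 28.4 bp for distinct fragments and 42.5 bp for dual-index libraries and for batch C, none of these 3 passing. In hotspots alone their median length was 79.5 bp higher than in wt (exact permutation p = 0.0179, the smallest possible). For tel1∆ the amount ranged from 0.94 to 2.01 with 1 library left out, and it did not pass without the whole cell extract (0.92), without calibration (0.21), or with dual-index libraries or batch C (0.95 in both). Its median length ranged from 0.75 to 17 bp with 1 library left out and from -2.75 to 33.75 bp under the other alternatives. It turned at 30 to 200 bp (-2.75 bp) and passed in hotspots alone (27.9 bp), as the share over 100 bp did (-3.34 and 12.9 points). With 1 library left out that share ranged from -4.49 to 4.48 points, turning without tel1∆ replicate 1 (-0.51), wt replicate 3 (-4.49) and rad50S replicate 2 (-0.21). Without calibration, the wt time course of amounts (r from 0.376 to 0.619 with 1 library left out) turned to r = -0.0639, and the rec114-8A amount (0.25 to 1.32) turned to -0.19. The wt length trend ranged from r = -0.749 to -0.413, and the rec114-8A length difference from 45.75 to 56.25 bp with 1 library left out and from 9.5 bp (30 to 200 bp) to 55 bp (hotspots alone) under the other alternatives. The rad50S difference between 6 and 4 h (0.43 to 1.28) was 1.41 without the extract and -0.57 without calibration. The period difference (-0.0167 to -0.0060 bp with 1 library left out) turned at 30 to 200 bp (0.0127), in hotspots alone (0.0027) and with a 15 bp running mean, where it passed (0.033, exact permutation p = 0.0357). After rapamycin, the log2 differences without the extract, without calibration and for short hotspot fragments were -0.51, -0.60 and 0.024 in RAD50 cells, -1.41, -0.54 and -1.01 in rad50S cells at 4.5 h, and -2.79, -2.61 and -2.03 at 5 h.

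For hotspots changed in processing mutants and without Tel1 (340 and 92), DESeq2 gave 600 and 270, 1000 bp bins 5339 and 2532 bins, distinct fragments 528 and 143, dual-index libraries 1053 and 227, batch C 1001 and 144, and batch as a covariate 889 and 167. Processing mutants had 177 at the threshold of 5, where fewer hotspots were tested, and 558 with the compared groups alone, and tel1∆ had 2 with short and 253 with long fragments. With 1 library left out the counts ranged from 56 to 441 for processing mutants, 0 to 421 for tel1∆, 0 to 348 for rec114-8A, and stayed at 0 for the other 2. For wt at 5 h against 3.5 h, DESeq2 gave 1 and dual-index libraries 2. For rad50S at 6 h against 4 h, DESeq2 gave 9, total counts 1, bins 3, the threshold of 5 gave 1, dual-index libraries 126 and the compared groups alone 761.

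With an estimated correlation, camera's adjusted p was 0.270, 0.270 and 0.457 for processing mutants (chromosomes 1, 3 and 6; near ends; highest decile), 0.446, 0.270 and 0.505 for tel1∆ (the same chromosomes; highest and lowest decile), 0.398, 0.360 and 0.398 for rec114-8A (in that order), 0.660 and 0.270 for wt (those chromosomes; near ends), and 0.193 and 0.660 for rad50S (those chromosomes; lowest decile). With the preset correlation, hotspots near ends in rad50S passed at 50 kb (0.0106), where an estimated one was not run. Among named hotspots, all without a call, that on chromosome 1 at 192438 turned for rec114-8A with dual-index libraries (-0.33), batch C (-0.28), batch as a covariate (-0.27) and without rec114-8A rad50S replicate 2 (-0.27 to 1.93 with 1 library left out), and for wt with short fragments (-0.051) and without replicate 2 at 3.5 h (-0.21 to 0.72). That on chromosome 3 at 211652 turned for rec114-8A with total counts (-0.56), distinct fragments (-0.28), long fragments (-0.088) and without rad50S replicate 2 (-0.15, against 0.22 as the highest with 1 library left out). That on chromosome 6 at 116251 turned for wt without replicate 1 at 3.5 h (-0.44 to 0.23) and for rad50S with distinct fragments (0.11).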

Other observations

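All tests of this part were chosen after the results were seen. Fragments that share a cut site should overlap by 2 bp, because Spo11 cuts the strands 2 bp apart and the overhang is filled in before sequencing. In all 28 libraries with active Spo11, an end overlapping another fragment's start by 2 bp was more frequent than any other offset. This held among fragments up to 100 bp and among those over 100 and up to 300 bp. It was 2.45 ± 0.452 (SD, n = 28) times as frequent as the median of the other offsets for the former and 2.16 ± 0.683 for the latter. In the 3 controls the ratio for the longer class was 1.01 ± 0.0136 (SD, n = 3). For the shorter class the controls' ratios did not separate from those of the active libraries. They were 2.18 and 0.389 in spo11Y135F replicates 1 and 2 and 1.77 in spo11∆, and 2 of these lay above the lowest active library. The most frequent overlap was 2 bp in only 1 of the 3 controls, against all 28 active libraries. In spo11∆ it was 39 bp, but the count pairs an end with every start within 40 bp, the fragment's own included. Overlaps as long as a short fragment thus also count that fragment itself, so the 39 bp tell nothing about neighbouring fragments. The S. kudriavzevii library had ratios of 3.62 and 3.33.

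The share of long fragments was larger in the widest than in the narrowest hotspots in each group that had both, except wt at 4 h. Fragments over 100 bp made up 47.9% of those in hotspots up to 150 bp wide and 64.7% of those in hotspots wider than 600 bp in rad50S at 4 h, 52.2% and 72.9% in rad50S tel1∆, 31.7% and 56.1% in rad50S at 6 h, 26.5% and 36.0% in tel1∆, and 33.0% and 67.1% in rec114-8A tel1∆. They made up 57.3% and 66.0% in mre11S and 62.7% and 68.3% in com1∆. In wt the values were 30.1% and 31.1% at 3.5 h, 15.6% and 14.8% at 4 h and 7.33% and 8.49% at 5 h. Across single hotspots, which are not independent replicates, width and long share correlated positively in wt too, with a Spearman rho of 0.148 to 0.314 against 0.473 in rad50S at 4 h, 0.355 in tel1∆, 0.554 in rec114-8A tel1∆, 0.316 in mre11S and 0.298 in com1∆. These values pool the libraries of a group, and no difference between strains was tested. The widths were set by the midpoints of these same fragments, long ones included, so the direction is not independent evidence.

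Chance was tested by regrouping libraries. With the 5 libraries of processing mutants as 1 group, 450 hotspots differed from wt, and 1 of the 56 splits of the 8 libraries into 5 and 3, the real one, gave as many; the highest of the others was 3. For tel1∆, 1 of the 60 splits within backgrounds gave as many as the real 92, and the highest of the others was 4. With 56 and 60 splits this makes chance less likely for both counts but does not exclude it. Nor is batch excluded, since the splits ignore it. Both batch A libraries of the second comparison lack Tel1 and all 5 libraries with Tel1 are of batch C, and in the first comparison 1 mutant library is of batch A. Within batch C, where no splits were run, 1001 and 144 hotspots passed. With 1 library left out, the counts fell to as few as 56 and 0.

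The spo11Y135F library replicate 1 held short fragments in hotspots with a 2 bp overlap ratio of 3.77 and counts that followed those of rad50S at 4 h (Spearman 0.773 across hotspots, which are not independent replicates). In spo11∆, which has no Spo11 and far fewer fragments, the ratio was 2.58, from 62 pairs, and the correlation 0.532, and in spo11Y135F replicate 2 they were 0.424 and 0.374. Among these spo11∆ fragments an overlap of 37 bp was the most frequent. A fragment of that length is counted there with its own start, so this value tells nothing about neighbouring fragments. Of the spo11∆ fragments of this kind 51.6% had the same start and length as a fragment of the active batch C libraries, and their source stays open. Misaligned spike-in fragments are not likely to be the only source in spo11Y135F replicate 1, since the library held 13.3 times as many of these fragments per S. kudriavzevii fragment as spo11∆ did. How far carry-over from the other sequenced libraries of batch C explains them was not settled. Of the 13646 distinct short hotspot fragments of spo11Y135F replicate 1, 43.3% had the same start and length as a fragment of those libraries. With a background of 31.7% taken out, this is at most 63.4%, a correction chosen after the first value had been seen. Fragments drawn from rad50S at 4 h replicate 2 gave 73.0% ± 0.432 (SD of 20 draws). The correction takes the background to be as dense in hotspots as outside them, which was not measured. Of all short fragments, hotspots held 15.8% in this library, 24.1% in spo11∆ and 32.8% in spo11Y135F replicate 2. A denser background would raise the 63.4%, so the comparison sets no limit on carry-over. Carry-over at the bench or from libraries not analysed here stays open too, and no biological explanation was tested.

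Many long fragments of wt had their midpoint outside the hotspots, up to 50.7% of all fragments in wt at 4 h replicate 1. DNA that Spo11 did not cut and that survived the exonuclease is not likely to be their only source, because the 2 bp overlap was in excess among them in all 8 wt libraries, with ratios from 1.05 (wt at 4 h replicate 1) to 4.39 (wt at 3.5 h replicate 1), while the highest ratio of a control was 0.992. A candidate explanation is Spo11 double cuts, in a mixture with uncut DNA whose share stays open. Fragments were placed by their midpoint, so the excess does not show whether the cuts themselves lay outside the called hotspots. The share of these fragments and their ratio were not correlated detectably over the 8 libraries (Pearson r = -0.389, permutation p = 0.342; Spearman rho = -0.405, permutation p = 0.327; r = 0.062, permutation p = 0.903, without the 2 libraries farthest from the median share).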
